A study of Mus musculus with 16 samples.

How the data were processed

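RNA from spleen cells of male C57BL/6 mice was sequenced in 16 libraries, 2 for each of 8 groups set by genotype (wild type or PKR knockout) and day of imiquimod treatment (0, 1, 2 or 5). Per the labels, spleens were passed through a 70-µm mesh, red cells were lysed, and cells of 2 mice were pooled for each library. Libraries were made from ribosomal RNA-depleted, stranded total RNA. The submitters' notes name the mm10 genome build, bcl2fastq 2.17.1.14, Trimmomatic, HISAT2 and TopHat, without saying what each tool did; the program that counted fragments and the annotation are not given in the sources used here.

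The deposited tables hold 142604 transcripts with a fragment count, FPM, FPKM and a transcript length each. Per the file headers the counts are fragments per transcript. FPM, as computed by the authors, equals the count over the library's total fragments, scaled as its name says. FPKM, as deposited, equals FPM per kilobase of the transcript length. The count divided by FPM gave library totals of 35026754 to 67333830 fragments. The summed transcript counts exceeded these totals by a ratio of 1.48 to 2.12, since the authors' counts place a fragment in every isoform it overlaps. Strandedness was checked on 25 pairs of single-exon transcripts, 1 lying wholly inside the other on the opposite strand. In all 25 the inner transcript had under 5% of the fragment count per base of the outer one (median 0.129%).

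Of the transcript identifiers, 99.1% were found in GENCODE mouse release 21. Because isoforms share fragments, 1 transcript was kept for each of 55291 gene symbols: the one with the highest mean count among protein-coding transcripts, or among all where a symbol had none. A protein-coding transcript was available for 21831 symbols, and 2214 symbols would have another transcript if any type could be chosen. This choice was made after the files had been seen; the sum of all isoforms and the choice among all types were run as alternatives. The kept transcripts held 19653279 to 51366713 counts per library. CPM are counts over the library's total fragments times its TMM factor, on the same scale as FPM.

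Genes were filtered with edgeR's filterByExpr, which left 18745. Differences were tested with edgeR 4.0.16 (TMM scaling, robust quasi-likelihood F test, 1 mean per group, 8 residual degrees of freedom, two-sided) and adjusted by Benjamini-Hochberg over all genes of a comparison, with calls at adjusted p under 0.05. The SE of a log2 change is its size over the square root of F. There were 14 comparisons: each treated day against day 0 within a genotype, knockout against wild type on each day, the 3 interactions and the genotype difference averaged over days. Adjusted p-values of single genes throughout come from this test unless another tool is named. Replicate numbers were not used to pair libraries across groups in the main test. Deviations between replicates correlated at -0.163 to 0.207 over 28 pairs of groups, with a median of 0.00573. The highest values, 0.21 on day 0 and 0.18 on day 2, were between the genotypes of the same day. Those of days 1 and 5 were -0.09 and -0.07. A weak link between replicates of the same day was thus not excluded on days 0 and 2.

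The comparisons, 41 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, then with the correlation estimated, and with fry; p-values were adjusted over the 41 lists of a comparison, 574 tests in all. Over the 14 comparisons the preset correlation gave 228 calls and the estimated correlation 1, that of endothelial and stromal cell markers between the genotypes on day 2. Member counts are given over all genes and adjusted over the list alone. Medians of lists with members at 0 in a group rest on fitted values.

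Named genes in each comparison were Eif2ak2, the 8 genes with the largest rise and the 8 with the largest fall past the threshold, up to 4 members of each list with the largest change or else the 2 with the smallest p, and a fixed panel of 16 cytokine, receptor, alarmin and stress genes. The ranked genes needed a mean FPKM of 1 or more in the higher group and both libraries of 1 group above both of the other; predicted genes, Riken clones, variable immunoglobulin and T cell receptor segments and pseudogenes were left out. For interactions and the averaged contrast 5 replaced 8; interactions had no requirement of separated libraries, and the averaged contrast needed it on 3 of the 4 days. Where all libraries of a group had no counts, the fold is a lower bound against a floor of 3 counts per library. Intervals of this kind cover counting error only.

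The Eif2ak2 transcripts were compared by exact two-sided permutation of genotype within days. Alternatives were no filter, FPKM of 2 or more in 2 libraries, DESeq2 1.42.0 with its own size factors, edgeR with those size factors, limma-trend on log2 of FPKM plus 1 (genes with FPKM of 0.5 or more), replicate number as a block, only the compared groups, and leaving out each library; isoform choice, removal of a GC trend (lowess span of 0.3) and leaving out the library labelled KO_D2 replicate 1 for every comparison were added after the data were seen. The DESeq2 dispersion search was given a tolerance of 1e-10 and up to 1000 iterations, set after the results were seen so that reruns give the same digits. The test was tried on simulated data: of 2-fold changes it recovered 58.6% between untreated groups, 32.3% in an interaction and 86.9% in the averaged contrast, and of 4-fold changes 88.9%, 70.7% and 98.0%, with 10, 10 and 7 false calls. Both sizes of change were simulated together, in groups that were otherwise alike, with no outlying library or GC trend. Recovery in the real comparisons, with fewer calls, may be lower. R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Circular RNAs, part of the study's stated purpose, were not analysed here because the deposited tables list linear transcripts. Some single-gene results, withheld for evaluation, are not reported here.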

Results

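Total RNA was sequenced from spleen cell suspensions of male C57BL/6 mice during daily treatment of the skin with 62.5 mg of 5% imiquimod cream, an agonist of Toll-like receptor 7 that is used to model psoriasis. Wild-type mice and mice lacking PKR, the kinase encoded by Eif2ak2 that is activated by double-stranded RNA, were sampled on days 0, 1, 2 and 5. Mice of day 0 received no cream. No group received cream without imiquimod, and none was left untreated until a later day. Changes from day 0 therefore cannot tell imiquimod from the cream, the handling or the day of sampling. Each of the 8 groups held 2 libraries, 16 in all, and each library pooled 2 spleens, so that n = 2 libraries per group throughout and the spread between mice within a pool was not measured. Library totals in the wild type were 44401257 and 67333830 fragments on day 0, 51481732 and 65035498 on day 1, 35546031 and 51996700 on day 2, and 40470938 and 40503939 on day 5. In the knockout they were 49927735 and 41010297 on day 0, 41538947 and 45617656 on day 1, 35596017 and 41695436 on day 2, and 40473833 and 35026754 on day 5. Levels are given as CPM, the count of 1 transcript per gene over composition-adjusted total fragments, as mean ± SD. Positions are on the mm10 build. Fold changes are log2 values with their standard error (SE).

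Day of treatment set the largest differences between the libraries. In a principal component analysis of the 2000 most variable genes, the first component (47% of variance) parted day 5, at 67.5 to 85.5, from the other days, at -46.5 to -2.10. The second component (35.5%) ran from day 0, at -60.1 to -53.8, to day 2, at 46.7 to 60.5, and the third held 7.91%. Replicates correlated at a Spearman rho of 0.986 to 0.993 across genes, and libraries of different groups at 0.915 to 0.993; genes are not independent replicates. The biological coefficient of variation was 13.1%, above counting error in every group, where the chi-square per gene between replicates was 13.1 to 75.6.

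The knockout was examined first through its own target gene. Eif2ak2 (ENSMUST00000024884.4, chromosome 17, 78852564 to 78882573) stood at 25.7 ± 1.24 CPM in the wild type and 13.9 ± 2.1 in the knockout on day 0, and at 98.3 ± 3.22 and 40 ± 4.22 on day 1. On day 5 the levels were 29.7 ± 0.686 and 17.3 ± 2.12. On day 2 they were 37.6 ± 6.85 and 34.5 ± 18.4, and the knockout pair was split, with 47.5 CPM in the library labelled KO_D2 replicate 1 and 21.5 in replicate 2. The knockout thus kept transcript at every time, and the labels do not say which part of the gene was deleted. Averaged over days, the full-length transcript was lower in the knockout by a log2 value of -0.80 (1.74-fold), with p = 0.00463 in an exact two-sided permutation of genotype within days (1296 splits). A transcript of the first 4 exons with a retained intron gave -1.14 (2.2-fold, p = 0.00309, the same exact test), and a transcript of exons 13 to 15 gave -0.56 (p = 0.0309, the same exact test). Without day 2, where the direction rests on the library labelled KO_D2 replicate 1, the full-length value was -0.99 (1.99-fold) and the exact p = 0.00926, the smallest that the 216 splits can give. In the test across all genes, with edgeR, none of these differences passed, with log2 values and adjusted p of -0.89 and 0.802 on day 0, -1.30 and 0.117 on day 1, -0.13 and 0.994 on day 2, and -0.78 and 0.654 on day 5. Averaged over days the edgeR value was -0.77 (adjusted p = 0.323), and it passed without the library labelled KO_D2 replicate 1 (-0.94, adjusted p = 1.27e-06) or without KO_D2 replicate 2 (-0.66, adjusted p = 0.000103), with 1.27e-06 to 0.955 over its alternatives. Without the library labelled KO_D2 replicate 1 the adjusted p was also 0.0238 on day 0, 0.00013 on day 1 and 0.0469 on day 5; over their alternatives the values ran from 0.0238 to 1.0, 7.95e-05 to 0.611 and 0.0469 to 1.0. The day 2 value was 0.33 without KO_D2 replicate 2 and -0.81 without the library labelled KO_D2 replicate 1.

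**Figure D1:**
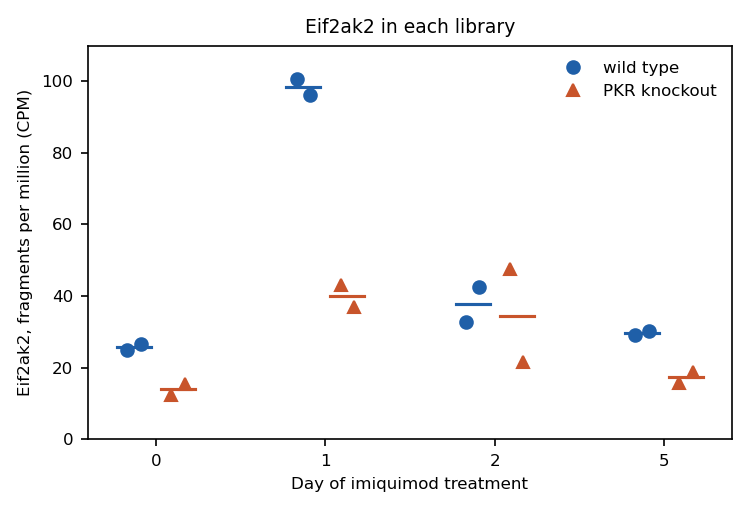
Eif2ak2 in CPM (linear axis) in each of the 16 libraries by day and genotype, with days evenly spaced and not to scale. The library labelled KO_D2 replicate 1 stands at 47.5 CPM, above both wild-type libraries of its day (32.8 and 42.5), and replicate 2 at 21.5.

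The changes in the wild type after 1 day of imiquimod included interferon-stimulated genes, of which 39 of 41 measured members rose (40 adjusted over the list alone) and none fell. The median log2 change was 2.31 (camera adjusted p = 8.67e-33, and adjusted p = 0.178 with an estimated correlation). Ifi44 went from 0.603 ± 0.0223 to 13.8 ± 2.82 CPM (log2 change 4.51, SE 0.449, adjusted p = 5.51e-06). Isg15, a ubiquitin-like modifier gene, went from 4.83 ± 0.14 to 65.8 ± 17.1 (log2 change 3.77, SE 0.232, adjusted p = 2.08e-08). Cxcl10, a chemokine that attracts T cells, rose by 3.98 on the log2 scale (adjusted p = 2.15e-08). Eif2ak2, itself an interferon-stimulated gene, rose by 1.93 (SE 0.289, adjusted p = 0.000308). Among sensors and regulators of double-stranded RNA, 10 of 21 rose and 4 fell (10 adjusted over the list alone for the rise; camera adjusted p = 0.00221, and adjusted p = 0.20 with an estimated correlation). Ifih1 rose by 2.07 and Tlr3 by 1.36. Of inflammatory cytokines and NF-kB targets, 13 of 25 rose (13 adjusted over the list alone), with a median of 0.83 (camera adjusted p = 0.000403, and adjusted p = 0.654 with an estimated correlation). Il6 went from 0.425 ± 0.163 to 4.87 ± 0.369 CPM (log2 change 3.48, SE 0.337, adjusted p = 3.1e-07). The chemokine gene Ccl2 rose by 3.69 (adjusted p = 0.000345). Ccl12 had no counts on day 0 and was at least 10.3-fold higher on day 1, against a floor of 3 counts per library.

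Proliferation genes rose throughout on day 1, 36 of 36 (36 adjusted over the list alone), with a median log2 change of 2.00 (camera adjusted p = 3.56e-44, and adjusted p = 0.157 with an estimated correlation). Gins2, of the replicative helicase, went from 1.46 ± 0.285 to 9.03 ± 0.924 CPM (log2 change 2.65, SE 0.199, adjusted p = 2.08e-08). Targets of ATF4, the transcription factor of the integrated stress response, rose in 25 of 31 cases and fell in 1 (26 adjusted over the list alone for the rise). Their median was 1.33 (camera adjusted p = 1.24e-13, and adjusted p = 0.157 with an estimated correlation). Asns, the asparagine synthetase gene, rose by 2.88 (SE 0.435, adjusted p = 0.000469). Aldh1l2, of mitochondrial folate metabolism, rose by 3.43 (adjusted p = 3.32e-05). Atf4 itself rose by 0.67 (adjusted p = 0.000179) and Ddit3 by 0.70 (adjusted p = 0.00758). The largest rises outside these groups included that of Saa3, an acute-phase protein gene, from 0.0887 ± 0.0317 to 12.5 ± 2.38 CPM (log2 change 7.04, SE 0.752, adjusted p = 5.65e-05). Tmed6 went from 0.076 ± 0.0176 to 7.02 ± 0.261 (log2 change 6.52, SE 0.348, adjusted p = 1.32e-09). Cfb, complement factor B, rose by 5.21 (adjusted p = 2.11e-05). Acod1, which makes itaconate in macrophages, rose by 5.34 (adjusted p = 0.00077), and Bcat1 by 5.01 (adjusted p = 6.19e-09).

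Several genes of macrophages and dendritic cells fell on day 1, though markers of marginal zone macrophages did not move as a list (2 of 8 fell and 2 rose; camera adjusted p = 0.38). Cd163, the haemoglobin scavenger receptor gene of macrophages, went from 6.7 ± 0.693 to 0.103 ± 0.0366 CPM (log2 change -6.02, SE 0.393, adjusted p = 4.47e-09). Trf, transferrin, went from 33.4 ± 4.21 to 2.65 ± 1.18 (log2 change -3.67, SE 0.26, adjusted p = 1.11e-07). Mrc1, the mannose receptor gene, went from 28.9 ± 5.32 to 1.79 ± 0.436 (log2 change -4.02, SE 0.316, adjusted p = 1.03e-06). Cd209d had no counts on day 1 and was at least 23.2-fold lower, against the same floor. Of red pulp macrophage markers, 7 of 17 fell and 4 rose (9 adjusted over the list alone for the fall). The median of these markers was -0.56 (camera adjusted p = 0.00279, and adjusted p = 0.681 with an estimated correlation). Conventional dendritic cell markers fell in 11 of 18 cases and rose in 3 (camera adjusted p = 2.01e-05, and adjusted p = 0.178 with an estimated correlation). Over that list alone 11 fell, and Clec9a was at -2.62 and Itgae at -2.56. T cell markers fell in 11 of 21 cases (12 adjusted over the list alone), with Themis at -1.40. Their median was -0.72 (camera adjusted p = 0.000946, and adjusted p = 0.703 with an estimated correlation). Mature neutrophil markers rose in 8 of 16 cases (8 adjusted over the list alone), with a median of 1.07 (camera adjusted p = 0.021, and adjusted p = 0.801 with an estimated correlation).

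Across 18745 genes, edgeR's quasi-likelihood test called 4107 higher and 4252 lower on day 1, of which 1613 and 1988 by 2-fold or more. Without WT_D0 replicate 2 the total of 8359 became 5856. Tnf (1.33, adjusted p = 0.0107) and Il1b (16.5 ± 1.5 to 74.3 ± 44.4 CPM, adjusted p = 0.0117) rose in the test on all libraries. The Tnf call ended without WT_D0 replicate 2 (adjusted p = 0.102) or WT_D1 replicate 1 (0.0525), with 0.000269 to 0.102 over its alternatives. The Il1b call ended without WT_D0 replicate 1 (0.0632), WT_D0 replicate 2 (0.0631) or WT_D1 replicate 1 (0.0754), with 0.000158 to 0.0754 over its alternatives. S100a8 (0.22, adjusted p = 0.765), S100a9 (0.28, 0.694), Hmox1 (-0.04, 0.873) and Ifng (-0.08, 0.871) did not pass. Il17a, Il17f, Il22, Il23a and Ifnb1 had too few counts to test at any time. The libraries of WT_D1 stood apart in composition, with scaling factors of 1.204 and 1.195 against 0.9331 to 1.069 in the others. Their summed transcript counts were 2.08 and 2.12 times their total fragments, against 1.48 to 1.80 in the others. With limma-trend on FPKM, which leaves out composition scaling and also differs in filter, offset and test, the median change of all genes was 0.172 in place of -0.0705, and 78.1% of 7534 calls were higher. With the size factors of DESeq2 in edgeR the median was -0.0592, and 50.2% of 8361 calls were higher. The medians of the lists described here kept their sign.

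On day 2 plasma cell and secretory genes rose in the wild-type spleen. Plasma cell markers rose in 16 of 18 cases (17 adjusted over the list alone), with a median of 2.57 (camera adjusted p = 4.92e-18, and adjusted p = 0.138 with an estimated correlation). Xbp1, the transcription factor of plasma cell secretion, went from 47.5 ± 6.15 to 516 ± 59.2 CPM (log2 change 3.44, SE 0.219, adjusted p = 9.05e-09). Derl3 went from 3.26 ± 1.29 to 67.3 ± 11.9 (log2 change 4.38, SE 0.238, adjusted p = 1.79e-09). Ighm, the IgM heavy chain, went from 2117 ± 250.0 to 19560 ± 4570 (log2 change 3.21, SE 0.233, adjusted p = 8.34e-09). Chaperones of the unfolded protein response rose in 19 of 20 cases (19 adjusted over the list alone), with Sdf2l1 at 3.35. The chaperone median was 2.18 (camera adjusted p = 4.91e-37, and adjusted p = 0.0712 with an estimated correlation). All 36 of 36 proliferation genes rose (36 adjusted over the list alone), with a median of 2.79 (camera adjusted p = 2.01e-58, and adjusted p = 0.0712 with an estimated correlation). Plk1, a mitotic kinase gene, went from 3.28 ± 0.794 to 34.9 ± 0.721 CPM (adjusted p = 2.96e-09). Replication-dependent histone genes rose in 26 of 26 cases (26 adjusted over the list alone; median 2.45; camera adjusted p = 6.41e-20, and adjusted p = 0.279 with an estimated correlation). ATF4 targets rose in 22 of 31 cases and fell in 2 (camera adjusted p = 3.67e-08, and adjusted p = 0.138 with an estimated correlation). Over the list alone 22 rose; Asns was at 2.90 and Atf4 at 0.52.

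T cell markers fell on day 2 in 21 of 21 cases (21 adjusted over the list alone) with a median of -2.34 (camera adjusted p = 9.89e-19, and adjusted p = 0.267 with an estimated correlation). Cd3e, a subunit of the T cell receptor complex, went from 30.7 ± 0.701 to 5.22 ± 0.212 CPM (log2 change -2.56, SE 0.349, adjusted p = 0.000139). Themis went from 33.7 ± 1.2 to 4.39 ± 0.0331 (log2 change -2.94, SE 0.335, adjusted p = 2.74e-05). Cytotoxic T and NK cell markers fell in 16 of 21 cases (16 adjusted over the list alone), with a median of -1.27 (camera adjusted p = 2.22e-06, and adjusted p = 0.284 with an estimated correlation). Gzmb, the granzyme B gene, rose by 1.85 (adjusted p = 1.13e-05). Markers of T helper 2 cells, mast cells, basophils and eosinophils fell in 15 of 17 cases (16 adjusted over the list alone), with Ear6 at -4.55 and Ccr3 at -3.49. This list had camera adjusted p = 4.08e-07, and adjusted p = 0.279 with an estimated correlation. Conventional dendritic cell markers fell in 13 of 18 cases (14 adjusted over the list alone), with Xcr1 at -2.57 (camera adjusted p = 4.99e-07, and adjusted p = 0.138 with an estimated correlation). Siglech, a surface receptor gene of plasmacytoid dendritic cells, went from 7.61 ± 1.56 to 0.243 ± 0.028 CPM (log2 change -4.97, SE 0.375, adjusted p = 9.42e-09). Apol7c went from 10.3 ± 0.315 to 0.297 ± 0.297 (log2 change -4.97, SE 0.43, adjusted p = 2.04e-07). Cd163 (-4.24, adjusted p = 2.39e-08) and Trf (-3.57, 7.4e-08) were still lower than on day 0.

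Among the largest day 2 rises was that of Tmed6, at 40.6 ± 4.36 CPM (log2 change 9.04, SE 0.331, adjusted p = 3.88e-12). Cdhr2, a protocadherin-family gene of epithelial brush borders, stood at 13.7 ± 6.1 (log2 change 6.90, SE 0.433, adjusted p = 2.07e-08). The tight-junction genes Cldn2 and Cldn7 had no counts on day 0 and were at least 125-fold and at least 31.1-fold higher, against 3 counts per library. Interferon-stimulated genes did not pass as a group, with 8 members higher, 9 lower and a median of -0.11 (camera adjusted p = 0.588); after a correction for GC content the median was 0.025. Il6 was higher than on day 0 (2.23, adjusted p = 4.46e-05). edgeR called 4175 genes higher and 4305 lower, and 2204 and 1952 of them by 2-fold or more. S100a8 (-2.02, adjusted p = 0.0174) and S100a9 (-1.93, 0.0191) fell in the test on all libraries. These calls ended without WT_D0 replicate 2 (0.112 and 0.128) or WT_D2 replicate 1 (0.109 and 0.117), with 0.000775 to 0.112 and 0.0012 to 0.128 over their alternatives. The fall of Ifng (-1.24, adjusted p = 0.0153) ended without WT_D0 replicate 1 (0.0735) or WT_D2 replicate 2 (0.141), with 0.00407 to 0.141 over its alternatives.

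By day 5 erythroid genes had risen together in the wild-type spleen. All 29 of 29 erythroid precursor markers rose (29 adjusted over the list alone), with a median of 3.77 (camera adjusted p = 5.46e-09, and adjusted p = 0.62 with an estimated correlation). Ank1, ankyrin of the red cell membrane, went from 12.8 ± 10.3 to 261 ± 21 CPM (log2 change 4.34, SE 0.808, adjusted p = 0.0030); the call ended when the compared groups alone were fitted (0.0724), with 1.03e-07 to 0.0724 over its alternatives. Genes of haem synthesis and iron handling rose in 21 of 23 cases (21 adjusted over the list alone), with a median of 2.73 (camera adjusted p = 6.95e-26, and adjusted p = 0.0555 with an estimated correlation). Steap3, an endosomal iron reductase gene, rose by 3.64 (adjusted p = 2.6e-06). All 36 of 36 proliferation genes rose (36 adjusted over the list alone; median 2.90; camera adjusted p = 5.57e-74, and adjusted p = 0.0555 with an estimated correlation). Of replication-dependent histone genes 26 of 26 rose (26 adjusted over the list alone; median 1.93; camera adjusted p = 9.25e-18, and adjusted p = 0.576 with an estimated correlation). Red pulp macrophage markers rose in 10 of 17 cases and fell in 2 (11 adjusted over the list alone for the rise; camera adjusted p = 0.0115, and adjusted p = 0.716 with an estimated correlation). Among them Cd5l went from 7.31 ± 0.747 to 31.4 ± 1.55 CPM (log2 change 2.10, adjusted p = 1.6e-06). Pparg, on the same list and also a gene of adipose tissue, went from 2.4 ± 0.0184 to 10.1 ± 0.772 (log2 change 2.07, adjusted p = 2.7e-06). Of markers of pancreas and adipose tissue that dissection can bring along, 2 of 5 measured rose (camera adjusted p = 0.0471, and adjusted p = 0.62 with an estimated correlation), Cela1 by 3.10 and Fabp4 by 1.66, both named after their values were seen. Plasma cell markers rose in 11 of 18 cases and fell in 2 (12 adjusted over the list alone for the rise; camera adjusted p = 0.00105, and adjusted p = 0.62 with an estimated correlation). The IgG heavy chain genes Ighg2c and Ighg2b rose by 4.39 and 4.15.

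Lymphocyte markers were lower on day 5. T cell markers fell in 21 of 21 cases (21 adjusted over the list alone; median -1.38; camera adjusted p = 5.62e-11, and adjusted p = 0.576 with an estimated correlation). Cd3e stood at 12.2 ± 1.13 CPM against 5.22 ± 0.212 on day 2. B cell markers fell in 17 of 21 cases and rose in 1 (19 adjusted over the list alone for the fall), with a median of -0.68 (camera adjusted p = 4.35e-07, and adjusted p = 0.62 with an estimated correlation). Among them Cr2, a complement receptor gene, was at -1.70, and Vpreb3 at -2.25. Interferon-stimulated genes fell in 21 of 41 cases and rose in 4 (23 adjusted over the list alone for the fall), with Mx2 at -1.60. Their median was -0.65 (camera adjusted p = 0.000752, and adjusted p = 0.716 with an estimated correlation). Tmed6 (log2 change 6.30, SE 0.356, adjusted p = 8.15e-10) stayed above day 0. Cdhr2 stood at 29 ± 2.85 CPM (log2 change 7.99, SE 0.428, adjusted p = 6.65e-09). Podxl, a sialomucin gene, rose by 7.84 (SE 0.669, adjusted p = 7.24e-07). edgeR called 4023 genes higher and 3383 lower, with 2251 and 1142 of them by 2-fold or more. The total of 7406 became 4680 without WT_D5 replicate 2. Hspa1a, a heat shock protein gene, was at -4.37 (adjusted p = 0.018). That call ended without WT_D0 replicate 2 (0.0519), WT_D5 replicate 1 (0.094) or WT_D5 replicate 2 (0.109), with 2.13e-09 to 0.109 over its alternatives. Il6 (-0.09, adjusted p = 0.89), Atf4 (0.01, 0.974), Tnf (-0.62, 0.209) and S100a8 (-0.18, 0.824) did not pass on day 5.

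In the PKR knockout, interferon-stimulated genes likewise rose on day 1, 36 of 41 (38 adjusted over the list alone), with a median of 1.99 (camera adjusted p = 1.19e-22, and adjusted p = 0.314 with an estimated correlation). Ifi44 went from 0.364 ± 0.111 to 8.59 ± 0.429 CPM (log2 change 4.53, SE 0.491, adjusted p = 1.07e-05). In these groups Isg15 went from 4.36 ± 0.117 to 46.8 ± 2.81 (log2 change 3.42, SE 0.233, adjusted p = 3.87e-08). The remaining Eif2ak2 transcript rose as well (log2 change 1.52, SE 0.292, adjusted p = 0.00169). Cytokine and NF-kB targets rose in 14 of 25 cases (14 adjusted over the list alone; median 0.92; camera adjusted p = 0.000846, and adjusted p = 0.577 with an estimated correlation). Il6 rose by 3.07 (adjusted p = 7.78e-07) and Il10, an anti-inflammatory cytokine gene, by 3.41 (adjusted p = 1.02e-05). All 36 of 36 proliferation genes rose (36 adjusted over the list alone; median 2.12; camera adjusted p = 2.49e-52, and adjusted p = 0.111 with an estimated correlation). ATF4 targets rose in 23 of 31 cases and fell in 3 (25 adjusted over the list alone for the rise; median 1.43; camera adjusted p = 5.31e-17, and adjusted p = 0.0767 with an estimated correlation). Among them Asns went from 1.6 ± 0.418 to 17.9 ± 2.21 CPM (adjusted p = 0.000169). Trib3, a pseudokinase gene that ATF4 induces, rose by 3.31 (adjusted p = 2.02e-06). T cell markers fell in 17 of 21 cases (18 adjusted over the list alone; median -1.15; camera adjusted p = 3.31e-07, and adjusted p = 0.493 with an estimated correlation). Conventional dendritic cell markers fell in 11 of 18 (11 adjusted over the list alone; median -1.08; camera adjusted p = 3.54e-05, and adjusted p = 0.255 with an estimated correlation).

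The largest single-gene rises in the knockout on day 1 included Saa3 (log2 change 7.20, SE 0.729, adjusted p = 3.78e-05) and Tmed6 (log2 change 6.92, SE 0.365, adjusted p = 3.89e-10). Spon1, an extracellular matrix protein gene, went from 0.325 ± 0.0179 to 24.5 ± 4.86 CPM (log2 change 6.22, SE 0.379, adjusted p = 5.99e-08). Slc7a3, a cationic amino acid transporter gene, went from 0.115 ± 0.0159 to 7.16 ± 0.189 (log2 change 5.91, adjusted p = 1.5e-08). Cd163 (log2 change -4.96, SE 0.381, adjusted p = 1.78e-08) and Siglech (log2 change -3.82, SE 0.326, adjusted p = 7.43e-08) fell. Crisp3 went from 2.02 ± 0.595 to 0.0545 ± 0.0099 CPM (log2 change -5.13, SE 0.506, adjusted p = 3.33e-07). edgeR called 3879 genes higher and 3915 lower, with 1717 and 1672 of them by 2-fold or more. With limma-trend on FPKM 64.1% of 6727 calls were higher. The rise of Tnf (7.69 ± 0.907 to 21.8 ± 9.47 CPM, adjusted p = 0.00637) ended without KO_D0 replicate 2 (0.059), with 0.000449 to 0.059 over its alternatives. That of Atf4 (0.50, adjusted p = 0.00228) ended without KO_D1 replicate 1 (0.0587), with 0.000249 to 0.0587.

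On day 2 in the knockout, plasma cell markers rose in 16 of 18 cases (16 adjusted over the list alone; median 2.89; camera adjusted p = 1.22e-15, and adjusted p = 0.126 with an estimated correlation). Unfolded protein response chaperones rose in 19 of 20 (19 adjusted over the list alone; median 2.07; camera adjusted p = 8.91e-32, and adjusted p = 0.0873 with an estimated correlation). Proliferation genes rose in 36 of 36 (36 adjusted over the list alone; median 3.14; camera adjusted p = 1.37e-58, and adjusted p = 0.0873 with an estimated correlation). Xbp1 went from 49.5 ± 1.19 to 557 ± 213 CPM (log2 change 3.49, SE 0.22, adjusted p = 5.91e-09). Fkbp11 rose by 4.99 (adjusted p = 5.64e-10). All 21 of 21 T cell markers fell (21 adjusted over the list alone; median -2.49; camera adjusted p = 8.22e-19, and adjusted p = 0.165 with an estimated correlation). Cd3e went from 29.7 ± 0.291 to 5.27 ± 3.78 CPM. Markers of T helper 2 cells, mast cells, basophils and eosinophils fell in 17 of 17 (camera adjusted p = 6.91e-08, and adjusted p = 0.171 with an estimated correlation), and Ccr3 was at -4.54. Over that list alone 17 fell. Ifng (log2 change -2.14, SE 0.405, adjusted p = 0.000246) fell and Il6 (log2 change 2.06, SE 0.334, adjusted p = 5.12e-05) rose. Tlr7, the receptor of imiquimod, fell (log2 change -0.62, SE 0.13, adjusted p = 0.000662). Cldn2 had no counts on day 0 and was at least 99.1-fold higher, against 3 counts per library. edgeR called 4508 genes higher and 4798 lower, with 2565 and 2239 of them by 2-fold or more. All of these directions include the library labelled KO_D2 replicate 1; without it 7663 genes were called in place of 9306.

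On day 5 in the knockout, all 29 of 29 erythroid precursor markers rose (29 adjusted over the list alone; median 4.29; camera adjusted p = 2.51e-08, and adjusted p = 0.73 with an estimated correlation). Epor, the erythropoietin receptor gene, went from 1.05 ± 0.238 to 38.5 ± 6.03 CPM (log2 change 5.20, SE 0.65, adjusted p = 0.000175). Ank1 went from 11.3 ± 3.21 to 426 ± 71.2 (log2 change 5.23, SE 0.845, adjusted p = 0.00112). Genes of haem and iron handling rose in 21 of 23 cases (21 adjusted over the list alone; median 2.99; camera adjusted p = 1.27e-27, and adjusted p = 0.0605 with an estimated correlation). All 36 of 36 proliferation genes rose (36 adjusted over the list alone; camera adjusted p = 2.69e-76, and adjusted p = 0.0605 with an estimated correlation). Replication-dependent histone genes rose in 26 of 26 (26 adjusted over the list alone; median 3.12; camera adjusted p = 1.68e-27, and adjusted p = 0.383 with an estimated correlation). T cell markers fell in 19 of 21 cases (21 adjusted over the list alone; median -1.31; camera adjusted p = 1.25e-07, and adjusted p = 0.73 with an estimated correlation). B cell markers fell in 18 of 21 (19 adjusted over the list alone; median -0.84; camera adjusted p = 1.47e-07, and adjusted p = 0.665 with an estimated correlation). Red pulp macrophage markers rose in 12 of 17 cases (12 adjusted over the list alone; median 0.93; camera adjusted p = 0.00272, and adjusted p = 0.73 with an estimated correlation), with Cd5l at 2.23. Of markers of pancreas and adipose tissue 2 of 5 rose here too, Cela1 and Fabp4, and the list did not pass (camera adjusted p = 0.0854). Crisp3 (log2 change -5.10, SE 0.531, adjusted p = 3.83e-07) and Apol7c (log2 change -3.56, SE 0.382, adjusted p = 2.11e-06) fell, as did Rgs13 (1.83 ± 0.649 to 0.177 ± 0.177 CPM, adjusted p = 1.45e-05). Snord17, a small nucleolar RNA, went from 356 ± 31.9 to 36.3 ± 0.599 CPM. edgeR called 4266 genes higher and 4148 lower, with 2563 and 1561 of them by 2-fold or more. The fall of Tlr7 (-0.61, adjusted p = 0.000897) ended without KO_D5 replicate 1 (0.0531), with 0.000181 to 0.0531 over its alternatives. That of Ifng (-1.18, adjusted p = 0.015) ended without KO_D0 replicate 2 (0.203) or KO_D5 replicate 1 (0.275), with 0.00129 to 0.275.

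**Figure D2:**
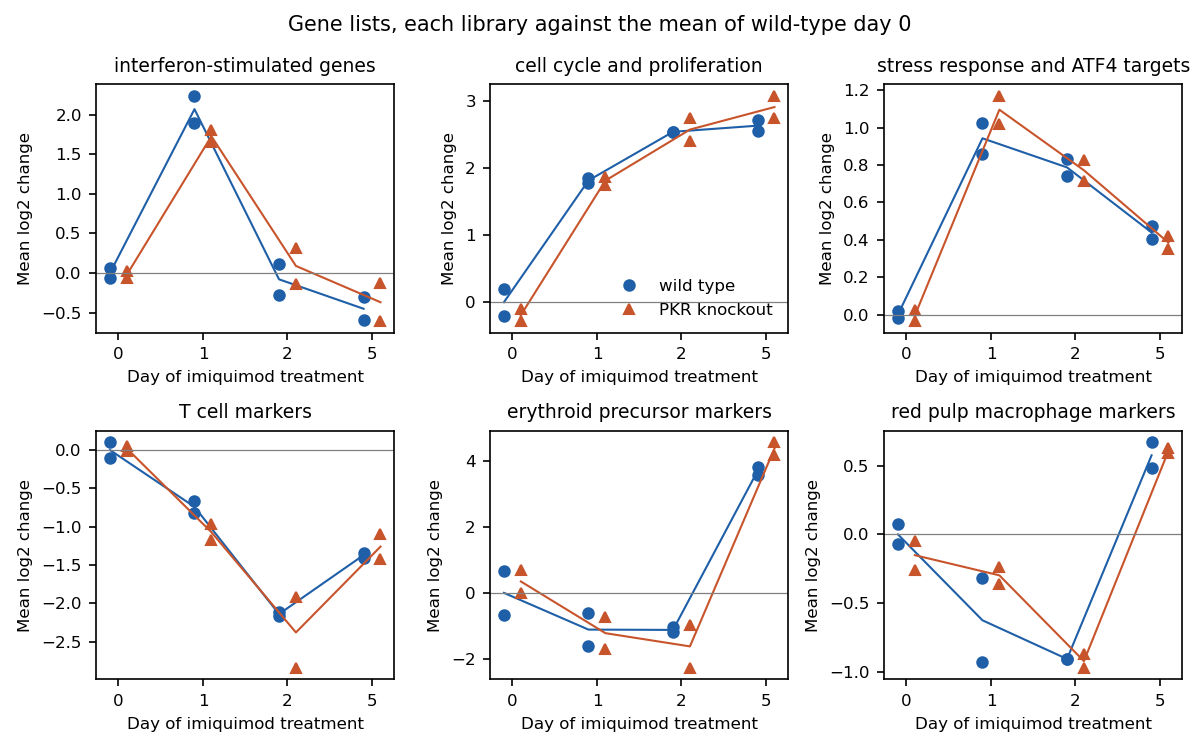
Score of 6 gene lists in each library (mean log2 difference from the mean of wild-type day 0, linear axis) by day, evenly spaced and not to scale. Interferon-stimulated genes stand at 1.65 to 2.24 on day 1, T cell markers at -2.84 to -1.92 on day 2, and erythroid markers at 3.58 to 4.56 on day 5.

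The responses of the genotypes were compared gene by gene. Across 18745 genes the log2 changes of knockout and wild type correlated at a Pearson r of 0.758 on day 1, 0.876 on day 2 and 0.859 on day 5, with Spearman rho of 0.743, 0.869 and 0.831; genes are not independent replicates. On day 1, 3035 genes were called higher in both genotypes and 2576 lower in both, where independent calls would share 849.9 and 888.1, and 24 were called in opposite directions. On day 2 the shared calls were 3651 and 3604 with 2 opposite, and on day 5 3293 and 2685 with 3 opposite. Of the genes called in the wild type, 94% on day 1, 99.2% on day 2 and 98.7% on day 5 had the same sign in the knockout. All day 2 values here include the library labelled KO_D2 replicate 1, where Eif2ak2 was not below the wild type. They were not computed without it.

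**Figure D3:**
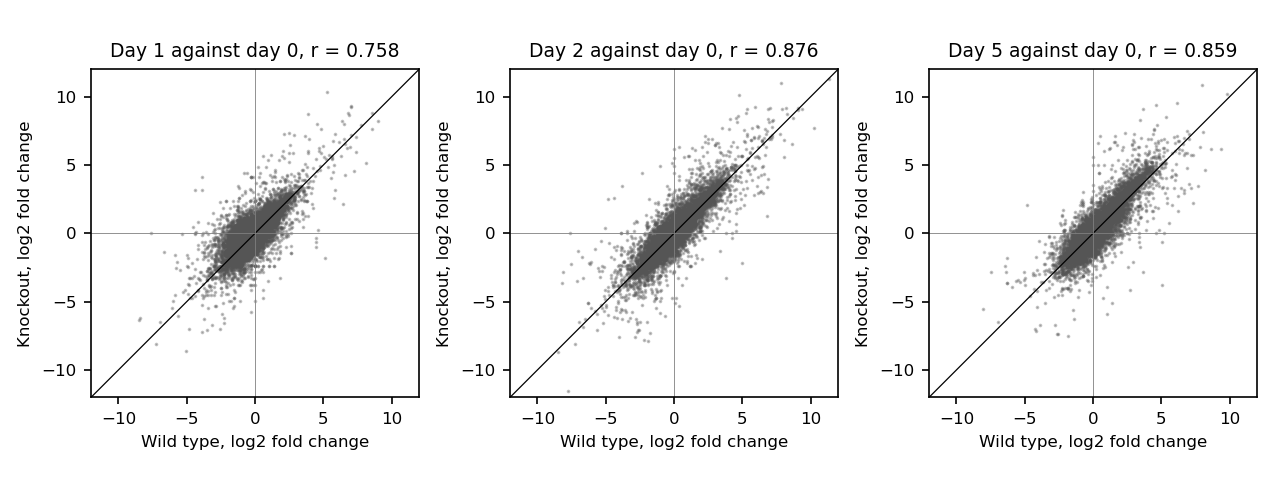
Log2 change from day 0 in the knockout against that in the wild type for 18745 genes on days 1, 2 and 5, both axes linear in log2. The points lie along the diagonal, with slopes of 0.798, 0.975 and 0.984. Day 2 includes the library labelled KO_D2 replicate 1.

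Few genes passed the threshold between knockout and wild type in the main test, and their counts depended on the settings described below. Of the 18745 genes, 5.94% had an unadjusted p under 0.05 by edgeR on day 0, 9.16% on day 1, 4.83% on day 2 and 6.28% on day 5. Few calls therefore do not show that differences were absent. The comparison alone cannot tell the loss of PKR from other differences between the knockout and wild-type mice. On day 0, before treatment, 4 genes were called, and 3 were higher in the knockout, against 27% of 63 with no filter and 5.36% of 56 without WT_D0 replicate 1. Ide, the insulin-degrading enzyme gene (ENSMUST00000131070.1, chromosome 19, 37268743 to 37330613), stood at 27.2 ± 3.9 CPM against 49.6 ± 0.647 in the wild type (log2 difference -0.87, SE 0.14, adjusted p = 0.0352). Zkscan3, a zinc finger repressor gene (ENSMUST00000117721.7, chromosome 13, 21389293 to 21402695), stood at 44.9 ± 5.15 against 25.3 ± 2.52 (log2 difference 0.83, SE 0.135, adjusted p = 0.0352). The other 2, named here only after their values were seen, were Ighv1-34 (1.38) and Gm26461 (0.92), both with adjusted p = 0.0352. No member of the lists was called over all genes, and no list passed with an estimated correlation. The preset correlation gave 5 lists, among them cytotoxic T and NK cell markers at a median of 0.27 and proliferation genes at -0.26, each with adjusted p = 0.998 with an estimated correlation. The count was 0 without KO_D0 replicate 1, 1 without WT_D0 replicate 2 or KO_D0 replicate 2, and 56 without WT_D0 replicate 1. The calls of Ide and Zkscan3 ended without WT_D0 replicate 2 (0.135 and 0.472), KO_D0 replicate 1 (0.148 for each) or KO_D0 replicate 2 (0.0997 and 1.0). Both also ended with FPKM of 2 or more (0.0648 and 0.072), the replicate block (0.0554 for each), limma-trend (0.329 and 0.308), only the compared groups (0.158 and 0.213) and the sum of isoforms (0.278 and 0.71), and that of Zkscan3 with any isoform (0.0529) and the GC correction (0.0911). Over the alternatives Ide had 1.0e-06 to 0.329, and Zkscan3 3.13e-05 to 1.0.

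On day 1 the knockout had 27 genes higher and 8 lower than the wild type. Of these 35, 14 were protein coding and 21 were of other types, many of them gene models of the annotation class TEC. Among the higher genes this class outnumbered the protein-coding ones, and no lower gene belonged to it. The balance of higher and lower genes turned with limma-trend on FPKM (16.7% of 6 calls higher) and without WT_D1 replicate 2 (33.3% of 6). Rnf157, a ubiquitin ligase gene (chromosome 11, 116336353 to 116413004), stood at 24.6 ± 0.939 CPM in the knockout and 9.14 ± 0.552 in the wild type (log2 difference 1.43, SE 0.171, adjusted p = 0.00104). Ide was lower again, at 37.1 ± 0.31 against 77.3 ± 0.633 (-1.06, SE 0.139, adjusted p = 0.00258). Gm6548, whose annotated end lies 607 bases from Eif2ak2, was also lower (-0.94, SE 0.143, adjusted p = 0.00648) and is named after its value was seen. Ly6c2, a surface protein gene of monocytes, stood at 119 ± 9.85 against 200.5 ± 30.2 CPM (-0.75, SE 0.145, adjusted p = 0.0401), and Ly6c1 at -0.86 (SE 0.155, adjusted p = 0.03). Both calls ended when any of the 4 compared libraries was left out and with FPKM of 2 or more (0.122 and 0.0626), and that of Ly6c2 also with limma-trend (0.114), the replicate block (0.0502) and the sum of isoforms (0.121). Without WT_D1 replicates 1 and 2 and KO_D1 replicates 1 and 2 in turn, the adjusted p of Ly6c2 was 0.188, 0.0761, 0.396 and 0.206. That of Ly6c1 was 0.127, 0.113, 0.195 and 0.266, and over their alternatives the values ran from 1.86e-06 to 0.396 and 6.36e-05 to 0.266. Atn1 (1.40) and Bicra (1.30, adjusted p = 0.03 and 0.0169) were higher, with calls that ended without any of the 4, at up to 0.294 and 0.25. These 2 also ended with limma-trend (0.126 and 0.114) and the GC correction (0.07 and 0.0686), and that of Atn1 with the sum of isoforms (0.188). The Rnf157 call ended with limma (0.0787; range 6.2e-16 to 0.0787). The Ide call ended without KO_D1 replicate 2 (0.0733; 8.12e-13 to 0.0733). The count of 35 became 6 without WT_D1 replicate 2, 8 without KO_D1 replicate 1, 4 without KO_D1 replicate 2 and 96 without the library labelled KO_D2 replicate 1.

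Among the lists on day 1, interferon-stimulated genes had a median difference of -0.34 between knockout and wild type (camera adjusted p = 1.19e-09, and adjusted p = 0.686 with an estimated correlation). None of its 41 members was called over all genes, and 3 were lower adjusted over the list alone. Ifit2, an antiviral protein gene, was at -0.70 (adjusted p = 0.0532). Red pulp macrophage markers had a median of 0.40 (camera adjusted p = 6.42e-06, and adjusted p = 0.686 with an estimated correlation). The T cell marker median was -0.40 (camera adjusted p = 6.42e-06, and adjusted p = 0.686 with an estimated correlation), with no member called. Il6 (0.33, adjusted p = 0.773), Hmox1 (0.53, 0.393) and Atf4 (-0.13, 0.80) did not pass. The pancreas markers Amy2a5, Pnlip and Cpb1, named after their values were seen, had no counts on day 0 in either genotype. On day 1 they stood at 0.341, 0.212 and 0.148 CPM in the wild type and at 1.64, 0.779 and 0.40 in the knockout. These levels are low, Cela1 and Fabp4 of that list are not given here, and tissue carried along in dissection was not tested. ATF4 targets had a median of 0.21 (camera adjusted p = 0.00266, and adjusted p = 0.686 with an estimated correlation), which was 0.000 with limma-trend on FPKM, where the median of all genes was -0.163.

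On day 2, edgeR called no gene between knockout and wild type; 906 had an unadjusted p under 0.05 and the smallest adjusted p was 0.264, while DESeq2 called 5 and limma 1. The count was 0 without the library labelled KO_D2 replicate 1, 1 without either replicate of WT_D2 and 40 without KO_D2 replicate 2. Endothelial and stromal cell markers had a median of 0.73 over 24 members, none called over all genes and 3 higher adjusted over the list alone (camera adjusted p = 8.19e-17, and adjusted p = 0.0179 with an estimated correlation). Stab2, a scavenger receptor gene of sinusoidal endothelium, was at 1.28 (adjusted p = 0.357). That comparison includes the library labelled KO_D2 replicate 1. Without it the list did not pass with an estimated correlation. A test with 1 knockout library cannot show whether the direction depends on the library left out. On day 5 a single gene was called, Ide, at 30.6 ± 0.134 CPM against 66.5 ± 8.93 (-1.12, SE 0.14, adjusted p = 0.0039). The Ide call ended without WT_D5 replicate 2 (0.245) or KO_D5 replicate 1 (0.103), with 3.0e-12 to 0.245 over its alternatives. On that day the count was 0 without WT_D5 replicate 2, 7 without WT_D5 replicate 1, 4 without KO_D5 replicate 2 and 11 without the library labelled KO_D2 replicate 1. On day 5 erythroid markers had a median difference of 0.71 (camera adjusted p = 2.99e-05, and adjusted p = 0.821 with an estimated correlation). Haem and iron genes had a median of 0.42 (camera adjusted p = 7.54e-13, and adjusted p = 0.528 with an estimated correlation; 7 higher adjusted over the list alone). Replication-dependent histone genes had a median of 0.62 (camera adjusted p = 1.35e-21, and adjusted p = 0.528 with an estimated correlation), with no member called over all genes.

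Whether the response itself differed between genotypes was tested as an interaction. From day 0 to day 1, 2463 genes (13.1%) had an unadjusted p under 0.05 by edgeR. After adjustment 32 genes responded differently, 24 of them with a higher and 8 with a lower change in the knockout. This balance turned when only the compared groups were fitted (27.8% of 18 calls higher) and with limma-trend on FPKM (20% of 5), and the 1 call without KO_D0 replicate 2 was lower. Bicra, of a chromatin remodelling complex, had a difference of 2.25 (SE 0.291, adjusted p = 0.015), and Atn1, a transcriptional corepressor gene, of 2.00 (adjusted p = 0.0422). The small nucleolar RNA gene Snora73b was at -1.35 (adjusted p = 0.0422) and its host gene Snhg3 at -1.13 (adjusted p = 0.0485); the 2 overlap on the same strand and can share fragments, so they are not separate evidence. The count rested on single libraries. It was 0 without WT_D1 replicate 2 or KO_D1 replicate 1, 1 without WT_D0 replicate 2 or KO_D0 replicate 2, 3 without WT_D1 replicate 1 and 4 without KO_D1 replicate 2. The count was 105 without KO_D0 replicate 1, 379 without WT_D0 replicate 1 and 89 without the library labelled KO_D2 replicate 1. After a correction for GC content it was also 0. The Bicra call ended with that correction (0.0708), with limma (0.0858) and without WT_D1 replicate 2 (0.075), KO_D0 replicate 2 (0.0964) or KO_D1 replicate 1 (0.146), with 4.69e-21 to 0.146 over its alternatives. The calls of Atn1 and Snora73b ended without WT_D0 replicate 2, KO_D0 replicate 2 or any library of day 1, and that of Snhg3 without these or KO_D0 replicate 1, with highest values of 0.302, 0.213 and 0.302. All 3 also ended with the GC correction (0.102, 0.0558 and 0.104), limma-trend (0.158, 0.116 and 0.156) and the sum of isoforms (0.147, 0.116 and 0.177). The calls of Snora73b and Snhg3 ended with FPKM of 2 or more (0.0804 and 0.0832), under which Atn1 was not tested, that of Atn1 with only the compared groups (0.0646) and that of Snhg3 with any isoform (0.0554). Interferon-stimulated genes had a median interaction of -0.34 on day 1 (camera adjusted p = 0.000449, and adjusted p = 0.956 with an estimated correlation). The interaction median of replication-dependent histone genes was 1.06 on day 5 (camera adjusted p = 2.74e-22, and adjusted p = 0.94 with an estimated correlation; 13 higher adjusted over the list alone). By edgeR no gene passed for a difference in response on day 2 (762 with an unadjusted p under 0.05, 3 by DESeq2, 0 by limma) or on day 5 (1483, 38 and 1). The smallest adjusted p by edgeR was 0.399 on day 2 and 0.055 on day 5. On day 2 the count became 8 without WT_D0 replicate 1 and 14 without KO_D2 replicate 2. On day 5 it became 41 without WT_D0 replicate 1, 3 without WT_D5 replicate 1, 1 without KO_D0 replicate 2, 4 without KO_D5 replicate 2 and 4 without the library labelled KO_D2 replicate 1.

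Averaged over the 4 days, 5 genes differed between the genotypes. Ide was lower by a log2 value of -0.76 (SE 0.0696, adjusted p = 2.95e-05) and Zkscan3 higher by 0.66 (SE 0.0681, adjusted p = 0.000112). Gm42047 (0.72), Gm6548 (-0.46) and Fgfbp3 (-1.13) were named after their values were seen, with adjusted p of 0.0267, 0.0267 and 0.0415. Fgfbp3 lies 349127 bases from Ide. The Ide difference passed in all 25 alternatives (8.47e-27 to 0.0076), and that of Zkscan3 in 24, ending with the sum of isoforms (0.124; 8.95e-16 to 0.124). Ide stood lower in the knockout on days 0, 1 and 5 and at 42.5 ± 9.11 against 42.8 ± 2.03 CPM on day 2, a pair that includes the library labelled KO_D2 replicate 1. In KO_D2 replicate 2 Ide was at 36.1 CPM, against 44.2 and 41.3 in the wild-type libraries. The difference was thus smaller on day 2 in that library too. The count of 5 became 2 without WT_D0 replicate 1, WT_D1 replicate 2, either replicate of WT_D2, WT_D5 replicate 2 or either replicate of KO_D0. It became 3 without WT_D5 replicate 1, either replicate of KO_D1 or KO_D5 replicate 1, 13 without WT_D0 replicate 2, 20 without the library labelled KO_D2 replicate 1 and 25 without KO_D2 replicate 2.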

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

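Of the tests here, the correction for GC content and the split of genes by GC content were chosen after the result was seen. With 2 libraries in each group, single outlying values within a group were not searched for.

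A difference between the genotypes in the response from day 0 to day 1, tested as an interaction with edgeR, singled out 32 genes. Bicra, at 2.25, and Atn1, at 2.00, had a higher change in the knockout, as did Mbd6 at 1.73, Bcl9l at 1.40 and Tnrc18 at 1.19. Snora73b at -1.35, Snora73a at -1.17 and Snhg3 at -1.13 had a lower one; the first 2 overlap Snhg3 on the same strand and can share its fragments, so the 3 are not separate evidence.

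The higher genes were rich in GC, with a median of 57.5% against 49.3% for all genes, and 15 of the 24 lay above the upper quartile of 54.2%. KO_D0 replicate 2 stood apart, with log2 levels -0.758 lower at 60% than at 40% GC against -0.247 to 0.298 in the other libraries, so its trend might have produced the pattern. Removing the trend took away 4.01% of the median absolute difference (1.47 to 1.41, with a median SE of 0.281 before and 0.268 after), and all 32 kept their sign, which argues against this trend as the whole source. The calls themselves ended, with adjusted p of 0.0558 to 0.171 in place of 0.015 to 0.0488, and the reason was not tested. Thinning to the smallest library kept 27 of 32 calls, which argues against depth as the whole source. A part played by GC content stays open. So do a genotype effect and a difference in the composition of the WT_D1 libraries, neither tested.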

How the results depend on the processing

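Leaving out the library labelled KO_D2 replicate 1 from every comparison, the choice of isoform, the sum of isoforms and the GC correction were chosen after seeing the data. Single-gene values and counts of genes in each direction were compared with the main test once for each setting. Under the settings chosen beforehand 20281 of these comparisons kept their side of the threshold or stayed within 1.5 times, in 724 a gene lost its call, in 169 it gained one and in 137 a count moved by more than 1.5 times. Under the added ones the numbers were 6611, 75, 16 and 21. A gene uncalled under both settings counts as kept. These tallies leave out the total counts, Eif2ak2 between the genotypes and the number of list calls. Of those, 172 comparisons stayed, 75 moved and 7 gained a call under the settings chosen beforehand. Under the added ones 58 stayed, 10 moved and 3 gained a call. Counts here and above were compared by size alone, so a count that stayed need not hold the same genes. With only the compared groups on day 0, 3 genes were called between the genotypes, and 0 of them were among the 4 of the main test. No named gene that passed in the main test or under an alternative changed sign between the 2; values that passed in neither did, such as Eif2ak2 on day 2. Of list medians called by camera, that of T helper 2, mast cell, basophil and eosinophil markers in the day 2 interaction changed sign, from -0.36 to 0.06 with limma-trend on FPKM. Totals within a genotype stayed within 1.5 times under all settings apart from 1 (4680 without WT_D5 replicate 2), but counts of lower genes moved further with limma-trend on FPKM (78.1% of 7534 calls higher in WT_D1 and 64.1% of 6727 in KO_D1) and without WT_D0 replicate 2, WT_D1 replicate 2, WT_D2 replicate 2, WT_D5 replicate 2, KO_D1 replicate 1 or KO_D5 replicate 1. Leaving out single libraries gave 5856 to 8844 (WT_D1), 6303 to 8823 (WT_D2), 4680 to 7804 (WT_D5), 5609 to 8208 (KO_D1), 7486 to 8288 (KO_D2; 7663 without the library labelled KO_D2 replicate 1) and 5833 to 8739 (KO_D5). Between the genotypes leaving out single libraries gave 0 to 56 on day 0, 4 to 96 on day 1, 0 to 40 on day 2, 0 to 11 on day 5 and 2 to 25 averaged, and for the interactions 0 to 379, 0 to 14 and 0 to 41. Eif2ak2 ran from -1.06 to -0.76 on day 0, -1.41 to -1.19 on day 1, -0.81 to 0.33 on day 2, -0.91 to -0.65 on day 5 and -0.94 to -0.66 averaged. A lone library was assumed to vary like the other groups.

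The counts of 4, 35, 0 and 1 between the genotypes on days 0, 1, 2 and 5, of 32, 0 and 0 for the interactions and of 5 averaged became 63, 432, 63, 208, 478, 19, 156 and 97 with no filter. With DESeq2 they became 11, 193, 5, 70, 217, 3, 38 and 13. With limma-trend on FPKM they became 2 on day 0, 6 on day 1, 1 on day 2, 6 on day 5, 5 and 1 for the day 1 and day 5 interactions and 2 averaged. With FPKM of 2 or more in 2 libraries they became 0 on day 0, 11 on day 1 and 1 for the day 1 interaction; with the replicate block, 0 on day 0. With only the compared groups they became 330 on day 1, 6 on day 5, and 18 and 1 for the day 1 and day 5 interactions. The sum of isoforms gave 0 on day 0, 12 on day 1, 3 for the day 1 interaction and 1 averaged, and the GC correction 70 on day 1 and 0 for the day 1 interaction. Eif2ak2 passed on day 1 with no filter (-1.35, adjusted p = 0.00521), DESeq2 (-1.29, 7.95e-05) and only the compared groups (-1.28, 0.000466), and averaged with no filter (-0.79, 0.0044) and DESeq2 (-0.76, 1.31e-06). Without the library labelled KO_D2 replicate 1 it passed on day 0 (-0.89, 0.0238), day 1 (-1.30, 0.00013), day 5 (-0.78, 0.0469) and averaged (-0.94, 1.27e-06). The number of list calls, 228, became 1 with an estimated correlation, 146 by fry and 252 without the library labelled KO_D2 replicate 1. For all of these the cause was not tested, apart from the fewer or more genes and libraries that a setting holds by construction. For the tests across all genes a pseudocount of 0.1 and quantile normalization were not run, since counts were the main unit; with that pseudocount on FPKM, Eif2ak2 was at -0.92, -1.50, -0.20 and -0.83 on days 0, 1, 2 and 5. Depth was not shown to limit the counts on day 1, which were 35 between the genotypes and 34 for the interaction after thinning to the smallest library. At 2 libraries per group, 58.6% of simulated 2-fold changes between untreated groups were recovered. The simulation had no outlying library or GC trend, so recovery in the real data may be lower.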

Other observations

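All tests in the paragraphs on the library labelled KO_D2 replicate 1 and the GC correction on day 1 were chosen after the result was seen; the test of depth and the splits of the samples were not.

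On day 1 in the wild type, nuclear-encoded oxidative phosphorylation genes rose in 31 of 32 cases (31 adjusted over the list alone; camera adjusted p = 3.24e-11, and adjusted p = 0.448 with an estimated correlation). Their median log2 change was 0.78, with Cycs, cytochrome c, at 1.40. Of 13 mitochondrially encoded genes 1 rose and 1 fell (camera adjusted p = 0.505), and their median of -0.20 became 0.10 with limma-trend on FPKM and 0.06 after the GC correction. Glycolysis and hypoxia genes rose in 14 of 24 cases and fell in 1 (14 adjusted over the list alone for the rise; camera adjusted p = 8.17e-07, and adjusted p = 0.20 with an estimated correlation). Vegfa, a vascular growth factor gene, rose by 1.86 and Hk2, hexokinase 2, by 1.78. In the knockout 27 of 32 oxidative phosphorylation genes rose (30 adjusted over the list alone; camera adjusted p = 2.16e-08, and adjusted p = 0.493 with an estimated correlation). Of glycolysis and hypoxia genes 14 of 24 rose in the knockout (15 adjusted over the list alone; camera adjusted p = 5.81e-08, and adjusted p = 0.216 with an estimated correlation). MHC class I presentation genes rose in 16 of 18 cases in the wild type (17 adjusted over the list alone; camera adjusted p = 1.37e-07, and adjusted p = 0.405 with an estimated correlation), with H2-T22 at 1.57. In the knockout 17 of 18 of them rose (17 adjusted over the list alone; camera adjusted p = 1.13e-06, and adjusted p = 0.478 with an estimated correlation). MHC class II genes fell on day 2 in 10 of 11 cases in the wild type (11 adjusted over the list alone; median -0.61; camera adjusted p = 0.0011, and adjusted p = 0.482 with an estimated correlation). In the knockout 11 of 11 class II genes fell, with the library labelled KO_D2 replicate 1 included (11 adjusted over the list alone; median -1.01; camera adjusted p = 2.48e-06, and adjusted p = 0.299 with an estimated correlation).

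Endothelial and stromal cell markers rose on day 2 in 14 of 24 cases in the wild type (14 adjusted over the list alone; camera adjusted p = 0.000547, and adjusted p = 0.279 with an estimated correlation). In the knockout 22 of 24 rose, a direction that includes the library labelled KO_D2 replicate 1 (22 adjusted over the list alone; camera adjusted p = 2.33e-07, and adjusted p = 0.10 with an estimated correlation). Col1a1, the type I collagen gene, went from 0.268 ± 0.00329 to 4.78 ± 1.05 CPM in the wild type (log2 change 4.15, SE 0.344, adjusted p = 2.23e-08). In the knockout it went from 0.194 ± 0.0537 to 5.17 ± 0.897 (log2 change 4.70, SE 0.373, adjusted p = 1.05e-08). Glucocorticoid-responsive genes fell on day 1 in 11 of 17 cases in the wild type (11 adjusted over the list alone; median -1.27; camera adjusted p = 4.0e-08, and adjusted p = 0.178 with an estimated correlation). In the knockout 11 of 17 of these fell (11 adjusted over the list alone; median -1.34; camera adjusted p = 2.81e-09, and adjusted p = 0.169 with an estimated correlation). Tsc22d3, a glucocorticoid-induced regulator gene, went from 382 ± 6.89 to 71.3 ± 8.15 CPM in the knockout (log2 change -2.42, adjusted p = 1.24e-08). On day 5 the metallothionein gene Mt2 was higher in the wild type (log2 change 4.98, SE 0.561, adjusted p = 4.43e-05). Cytosolic ribosomal protein genes fell on day 5 in 22 of 39 cases in the knockout (23 adjusted over the list alone; median -0.43; camera adjusted p = 0.000228, and adjusted p = 0.747 with an estimated correlation), with Rps20 at -1.14.

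Eif2ak2 in the library labelled KO_D2 replicate 1 stood at 47.5 CPM, above both wild-type libraries of its day (32.8 and 42.5). Wild-type RNA in this library, as from a mixed or mislabelled pool, is a candidate explanation: 9 other genes that parted the genotypes on days 0, 1 and 5 had a median position of -0.134 in it (0 is the wild-type mean, 1 the knockout level), against 0.676 in KO_D2 replicate 2. The 9 are not all separate, since Gm6548 lies 607 bases from Eif2ak2 and Fgfbp3 349127 from Ide; with 1 gene per chromosome and none from that of Eif2ak2, the medians over 5 genes were 0.047 and 0.517. The 9 parted the genotypes unevenly in KO_D2 replicate 2 as well, from -0.562 for Rnf157 to 1.229 for Fosb, with Ide at 0.243. This limits what their positions can show. Of these 9, Fosb went the other way in the library labelled KO_D2 replicate 1, at a position of 6.37 with 6.49 CPM against 119.7 and 94.1 in the wild type. The library also stood apart from the 3 others of its day in the mean scores of whole lists: immediate early and dissociation stress genes (-1.254 against -0.207 to -0.083), erythroid precursor markers (-2.269 against -1.196 to -0.972), T cell markers (-2.843 against -2.17 to -1.92) and glucocorticoid-responsive genes (-1.294 against -0.764 to -0.604). It thus differed from both genotypes of its day in more than the genes that part them, and the source of that was not tested. A swap with a library labelled WT_D2 is argued against by the ratio of 0.772 between the Eif2ak2 levels of those libraries, and a stronger interferon response by interferon-stimulated genes that were -0.518 (SD 0.487) against replicate 2, where Eif2ak2 was at 21.5 CPM. A mixed pool and a wrong label were not told apart. An even mix of the genotypes would lie between their levels, whereas Eif2ak2 lay above both wild-type libraries, but this rests on 1 library. No other biological difference between the pooled mice was tested.

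The 35 genes called between knockout and wild type on day 1 might follow GC content or depth. With the GC trend of each library removed, 91.4% of the calls (32 of 35) were kept and 70 were made, and with all libraries thinned to 35026754 fragments 82.9% (29 of 35) were kept, which argues against either as the whole cause. The composition of the WT_D1 libraries and the genotype itself stay open, the former untested. Those libraries had scaling factors of 1.204 and 1.195. Their summed transcript counts were 2.08 and 2.12 times their total fragments, against 1.69 and 1.80 in KO_D1.

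Chance was not excluded for the 5 genes called between the genotypes averaged over days. Of 100 ways to assign genotype labels within days, the real one included, 8 gave 5 or more calls, and the highest of the others gave 187. A split that calls so many points to a structure of the samples, and no test here identified it. Ide passed in all 25 alternatives of that comparison, but these reuse the same libraries and so cannot exclude chance for Ide.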
